A study of Homo sapiens with 26 samples.

How the data were processed

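Messenger RNA and REST binding were measured in a pair of human glioma cell lines: U-87 MG, called IDHwt below, and an IDH1-mutant isogenic U-87 line, called IDHmut. REST is a transcriptional repressor of neuronal genes. RNA was sequenced from cells transfected with a control siRNA (siCTRL) or a REST-targeting siRNA (siREST), with 3 libraries per line and siRNA, and from untreated cells, with 3 libraries per line. REST chromatin immunoprecipitation sequencing (ChIP-seq) was done on 2 samples per line. The 4 input samples have no file of their own and were not analysed here. The labels do not say whether replicates are separate cultures, so they may be technical.

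Groups were taken from the sample titles. For the siREST libraries of IDHwt and the siCTRL libraries of IDHmut, the transfection label names the other siRNA than the title. REST levels in the libraries go with the titles. A genotype label also calls the IDH1-mutant isogenic line an IDH1 knockdown, and the deposited files cannot settle which name is right.

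Per the labels, RNA libraries were made with a stranded mRNA kit, reads were trimmed with Trimmomatic, aligned to hg38 with STAR, counted with HTSeq and normalized with DESeq2; ChIP reads were aligned with BWA, peaks were called with MACS2 and annotated with ChIPseeker. No versions are given. Each deposited RNA table holds a signal per gene and library, which the authors made by dividing read counts by DESeq2 size factors. Dividing by a factor found per library returned whole read counts, to a relative tolerance of 1e-06, for 100% of values, which were used only for depth and for the edgeR and DESeq2 alternatives. The siRNA table (12 libraries) and the untreated table (6 libraries) were normalized separately and were tested separately. The deposited peak lists give for each peak a score, a fold enrichment, which is the authors' ratio of ChIP to background signal, and a -log10 p and -log10 q from MACS2. Fold enrichment is the authors' own value and was used only to rank or group peaks within a list. Coordinates are hg38, 1-based.

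Recovered reads per library ranged from 14873762 to 18954580 in the siRNA table and from 15114963 to 18659419 in the untreated table. The untreated table has 417 entries with no gene identifier, which were left out. Of the gene identifiers, 60261 of 60617 (99.4%) in the siRNA table and 57357 of 57998 (98.9%) in the untreated table matched the gene-name reference. Symbols and gene positions came from that reference and from a RefSeq gene table of GRCh38.p14, which placed 13808 of the 14741 genes tested in the siRNA table. Intervals given for shares are Wilson 95% intervals and cover counting error only.

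Genes with at least 10 normalized counts in at least 3 libraries were kept. Log2 of the normalized count plus 1 was fitted with limma 3.58.1 (R 4.3.3) with a mean per group and a trended prior variance. All 12 siRNA libraries were in 1 fit. The contrasts were siREST against siCTRL in each line, the difference between those changes (interaction), and IDHmut against IDHwt in siCTRL and in untreated libraries. P values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p under 0.05 were called. Fold changes are log2 values with their standard error (SE); levels are mean normalized counts ± SD with n = 3. Single-gene levels of REST and IDH1 were also compared by two-sided exact permutation tests, which cannot give a p under 0.1 with 3 libraries against 3.

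Same-numbered libraries were checked for pairing from the correlation of their deviations from group means across genes. It was 0.335, 0.120 and 0.332 between siREST and siCTRL in IDHwt, and 0.402, 0.167 and 0.361 in IDHmut, so counts with the replicate number as a block are given beside the siREST results. Between lines it was 0.209, 0.068 and 0.149 in siCTRL and 0.061, 0.048 and 0.127 in untreated libraries, and the block was kept as an alternative.

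Genes named in the text were REST and IDH1, and the 8 largest rises and 8 largest falls of each siREST contrast and of the untreated contrast (4 and 4 in siCTRL). They had to be called, have a mean of at least 50 normalized counts, show no overlap between the groups' libraries and carry a symbol that is not a clone or locus name. For gene lists, up to 4 members with the smallest p are named. The 8 genes with a reproducible REST peak in both lines and the largest mean rise were also named, as were the 5 strongest reproducible peaks and up to 5 line-specific peaks per line. Rules, lists, tests and alternatives were set before the data were examined, except where the text says otherwise. The division of regions by fold quartile and of bound genes by fold tertile, the joint count of genes bound in both lines, the comparison by chromosome and the Fisher tests between siREST and line calls were added after the data were seen.

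A REST region was reproducible when merged peaks of both samples of a line overlapped by at least 1 bp (bedtools 2.31.1). It was line-specific when it overlapped no peak in either sample of the other line. The RefSeq table gives no strand, so a gene counted as bound when a reproducible region lay within 1 kb of either end of the gene, in place of the planned transcription start site. Shares of bound genes were compared by Fisher's exact test, two-sided, over genes tested and placed, and odds ratios carry 95% intervals. The planned search for RE1 motifs, the DNA element REST binds, was not run because no genome sequence was used here.

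There were 27 gene lists. A list of microglia and blood cell markers had too few expressed genes to test. The other 26 were tested by camera with a preset correlation between genes, and again with an estimated correlation. Fry tested whether the genes of a list changed in a shared direction, and whether they changed in either direction. Neither form compares the list with other genes. They covered REST neuronal targets, the REST corepressor complex, neurogenic transcription factors, astrocyte, oligodendrocyte, epithelial and endothelial markers, matrix degradation and invasion, extracellular matrix structure, mesenchymal transition, integrins and adhesion, S phase, G2 and M phase, p53 targets, interferon response, NF-kB cytokines, hypoxia, integrated stress response, cholesterol biosynthesis, TGF-beta and YAP targets, 2-oxoglutarate-dependent dioxygenases, DNA methylation factors, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, immediate early genes and replication-dependent histones.

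The fit was tested on simulated data with 200 changed genes. These were drawn from genes with a mean of at least 50 normalized counts, so recovery of genes with lower counts was not tested. At a 2-fold change it recovered 96% of genes for siREST in IDHwt, 98% in IDHmut, 74% for the interaction, 86% for the siCTRL line contrast and 96% for the untreated one. At a 1.5-fold change these shares were 84%, 72%, 40%, 74% and 56%. False calls made up 3.65% to 6.38% of calls. The peak functions gave 0 mismatches on simulated intervals.

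Alternatives were TMM scaling, prior counts of 0.5 and 5, no filter or a mean of at least 50, edgeR 4.0.16, DESeq2 1.42.0, a replicate block, fits on the compared groups alone, a minimum 2-fold change, each library left out in turn, a 50% reciprocal peak overlap, peaks with a -log10 q of at least 5, single ChIP samples and distances of 5 and 10 kb.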

Results

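The data were 18 RNA-seq libraries and 4 REST ChIP-seq peak lists from U-87 MG glioma cells (IDHwt) and an IDH1-mutant isogenic U-87 line (IDHmut). Each line had 3 untreated, 3 siCTRL and 3 siREST RNA libraries and 2 ChIP samples. Library depth was 14873762 to 18954580 recovered reads in the siRNA table and 15114963 to 18659419 in the untreated table. The siRNA and untreated tables were normalized separately, so levels are compared only within a table.

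The siRNA lowered REST mRNA to a similar level in both lines. REST (ENSG00000084093; chromosome 4, 56907900 to 56935844) fell from 950.8 ± 51.7 to 303.8 ± 15.2 normalized counts (SD, n = 3) in IDHwt, which is 32.0% of control. In IDHmut it fell from 972.3 ± 20.9 to 267.9 ± 44.2, or 27.6% of control. The log2 fold changes were -1.64 (SE 0.097, adjusted p = 5.14e-07) and -1.87 (SE 0.097, adjusted p = 1.16e-07). The exact permutation test gave p = 0.1 in each line, the smallest it can give. The REST change did not differ detectably between lines, with a difference of -0.23 and an adjusted p of 1.0.

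REST mRNA without knockdown was close between the lines, while IDH1 mRNA was lower in IDHmut. In siCTRL libraries the log2 difference of IDHmut against IDHwt in REST was 0.03 (adjusted p = 0.802). In untreated libraries REST was 1193 ± 164 in IDHmut and 964.6 ± 30.6 in IDHwt (SD, n = 3), a log2 difference of 0.30 (adjusted p = 0.0481) that lost its call under 7 alternatives. IDH1 (ENSG00000138413; chromosome 2, 208236227 to 208255071) was 1358 ± 286 in IDHmut and 2611 ± 275 in IDHwt with siCTRL, a log2 difference of -0.96 (adjusted p = 0.000989). Untreated, it was 725.6 ± 80.8 against 995.9 ± 153, a log2 difference of -0.45 (adjusted p = 0.0216) that lost its call under 3 alternatives. The siREST siRNA changed IDH1 by 0.08 in IDHwt and 0.02 in IDHmut on the log2 scale, with adjusted p values of 0.876 and 0.989.

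**Figure D1:**
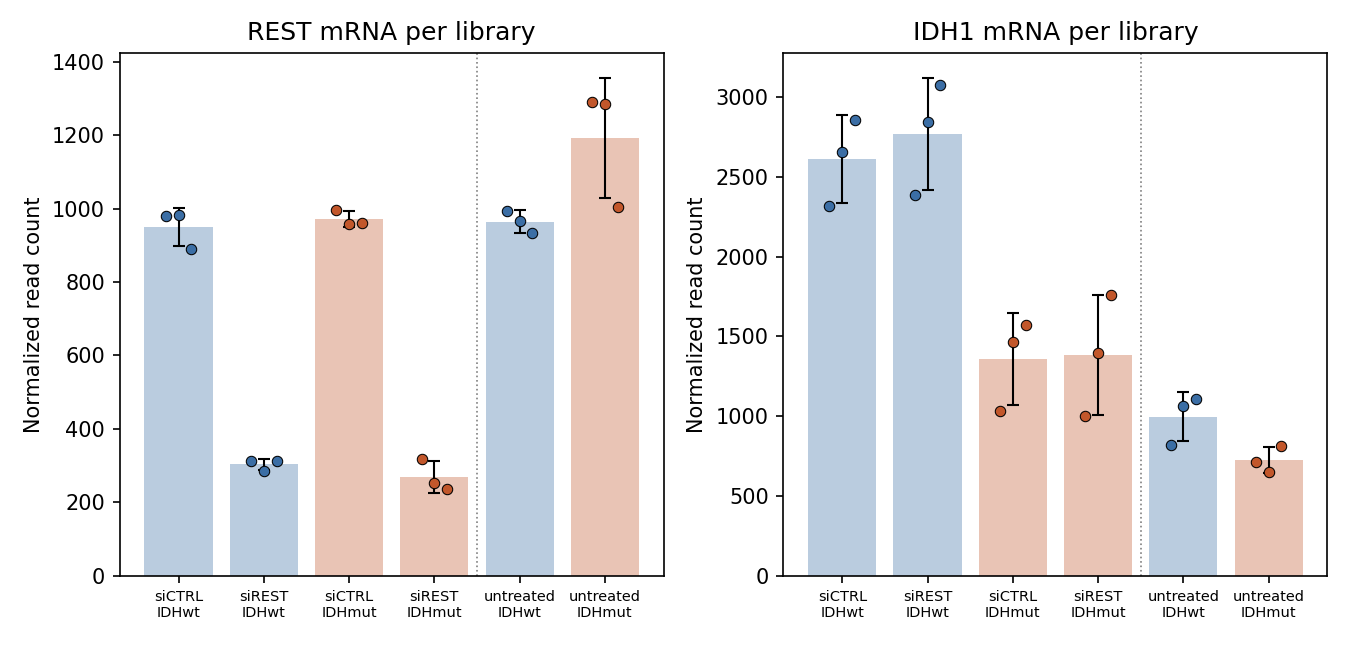
Normalized read counts of REST and IDH1 in each library (points), with the group mean (bar) and SD (error bar), n = 3; blue is IDHwt, orange is IDHmut, and the dotted line parts the 2 separately normalized tables. REST lies between 234.6 and 318 in siREST libraries and between 891.1 and 996.4 in siCTRL libraries.

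Which genes change when REST is knocked down in IDHwt was asked by comparing siREST with siCTRL. Of the genes named, CHRNB2 encodes a nicotinic acetylcholine receptor subunit, and UNC13A and SYP encode proteins of synaptic vesicle release. SCG2 and VGF encode proteins of dense-core secretory granules. BSN encodes a presynaptic scaffold, AP3B2 a neuronal vesicle adaptor and TMEM198 a membrane protein.

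CHRNB2 (ENSG00000160716; chromosome 1, 154567778 to 154580013) rose from 0.972 ± 0.923 to 184.1 ± 5.42 normalized counts (SD, n = 3), a log2 fold change of 6.68 (SE 0.367, adjusted p = 2.49e-07). VGF (ENSG00000128564; chromosome 7, 101162509 to 101169952) rose from 812 ± 18.6 to 13850 ± 1166, a log2 fold change of 4.09 (SE 0.076, adjusted p = 1.61e-12). The log2 fold change was 6.58 for UNC13A, 5.73 for SYP, 5.35 for SCG2, 4.48 for TMEM198, 4.17 for BSN and 3.79 for AP3B2. UNC13A had a mean of 1.08 counts in siCTRL, so the added count of 1 affects the size of its change and of that of CHRNB2. Falls were smaller. After REST itself came TAGLN3 at -1.43, DRAM1 at -1.31, SEMA3A at -1.19, KCNS3 at -1.11, LAT2 at -1.04 and ACP3 at -0.98. The pseudogene RPSAP52 was listed at -0.97, which is uncertain because its reads can come from its parent gene. The calls of ACP3, TAGLN3 and LAT2 were lost under 7, 6 and 2 alternatives.

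Of 14741 genes, 256 rose and 200 fell. With the replicate number as a block, 807 rose and 801 fell, among them all 456 genes called without it. Leaving out a library gave 194 to 406 calls, with 194 without siREST_IDHwt replicate 2, 229 without siCTRL_IDHwt replicate 3, 254 without siCTRL_IDHwt replicate 2 and 287 without siCTRL_IDHwt replicate 1. At least a 2-fold change was seen for 75 rising and 12 falling genes (104 and 26 with the block). The 12 became 5 without siREST_IDHwt replicate 2 and 6 without siCTRL_IDHwt replicate 2 or 3.

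The same question in IDHmut gave largely the same leading genes. UNC13A rose by 6.57, CHRNB2 by 6.54, SYP by 5.62, SCG2 by 4.20 and VGF by 3.85 on the log2 scale. STMN3, a neuronal microtubule regulator, rose by 5.61, RUNDC3A by 4.49 and CHGB, a secretory granule protein, by 3.96. Mean siCTRL counts were 2.11 for UNC13A, 4.09 for CHRNB2 and 3.82 for STMN3, so the added count affects the size of these rises. For STMN3 it was 4.75 with a prior count of 5. After REST, the largest falls were DRAM1 at -1.19, SEMA3A at -0.98, KCNS3 at -0.92, HSD17B10 at -0.81 and CDCA2 at -0.76. The pseudogenes CDHR17P (-0.75) and HMGN1P36 (-0.73) were also listed, which is uncertain because related genes can share their reads. Calls were lost under 6 alternatives for HMGN1P36, 5 each for SEMA3A and CDHR17P and 1 for KCNS3.

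In IDHmut 145 genes rose and 81 fell. With the replicate block 491 rose and 421 fell, including all 226 genes called without it. Leaving out a library gave 105 to 599 calls: 599 without siREST_IDHmut replicate 1, 105 without siREST_IDHmut replicate 2, 112 without siREST_IDHmut replicate 3, 121 without siCTRL_IDHmut replicate 2 and 145 without siCTRL_IDHmut replicate 3. A fit of the 2 groups alone called 112 genes. At least a 2-fold change was seen for 54 rising and 4 falling genes (73 and 18 with the block). The 4 became 14 without siREST_IDHmut replicate 1 and 8 without siCTRL_IDHmut replicate 1.

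The changes were largely shared between the lines in direction. Some REST targets differed in size when adjusted over their list alone. None passed over all genes in the main limma fit, while a few did under alternatives given below. Of the calls, 125 genes rose in both lines where 2.52 would do so if the lines were independent, 70 fell in both where 1.10 would, and 0 moved in opposite directions. Of the IDHwt calls, 42.8% were also called in IDHmut and 99.1% had the same sign. Across the genes called in IDHwt, the changes in the lines had a Pearson r of 0.94 and a slope of 0.86; over all genes r was 0.64. These are correlations across genes, which are not independent replicates.

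**Figure D2:**
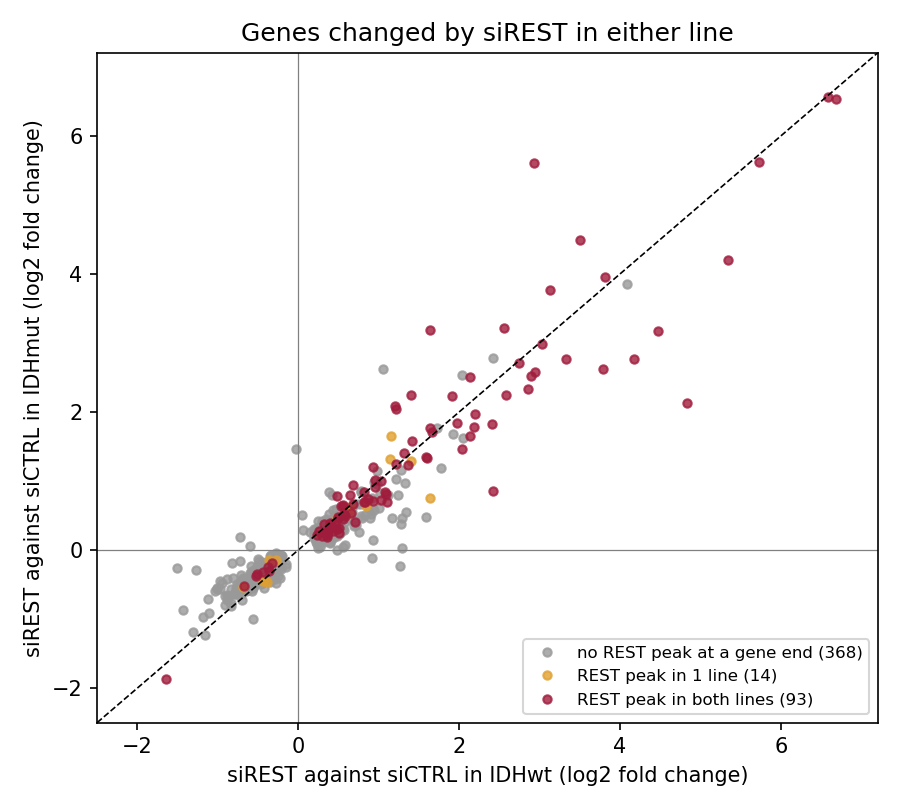
The log2 fold change of siREST against siCTRL in IDHwt (x axis) and IDHmut (y axis) for each gene called in either line and placed on the genome; colours mark a REST peak within 1 kb of a gene end in both lines (93 genes), in 1 line (14) or in neither (368), and the dashed line marks equal change. The genes with the largest rises in both lines carried such a peak in both, except VGF, and peaks further inside a gene were not counted.

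Whether the lines responded differently to siREST was tested by the interaction. By limma, 0 genes passed, with a smallest adjusted p of 0.0796, while 283 genes had an unadjusted p under 0.05. The edgeR count was 0 and the DESeq2 count was 4; with the replicate block limma called 4. The genes called by DESeq2 and by the block were BSN, AP3B2, TMEM198 and GDAP1, chosen here after their values were seen. BSN rose by 4.17 in IDHwt and 2.77 in IDHmut (block adjusted p = 0.00236), AP3B2 by 3.79 and 2.62 (0.0138) and TMEM198 by 4.48 and 3.18 (0.0409). GDAP1 rose less in IDHwt, by 1.21 against 2.08 (block adjusted p = 0.00236). Their adjusted p values without the block were 0.0796 for BSN and GDAP1, 0.105 for AP3B2 and 0.143 for TMEM198. Without siCTRL_IDHwt replicate 3, 2 genes passed, TMEM198 and STMN3. STMN3 was also the 1 gene called with a prior count of 5 (limma adjusted p = 0.00276). It rose less in IDHwt, by 2.93 against 5.61 in IDHmut. Among the 39 tested REST neuronal targets, 3 moved higher and 5 lower in IDHmut than in IDHwt adjusted over the list alone, and 4 and 6 with the replicate block (fry test of changes in either direction, adjusted p = 1.37e-07, and 3.32e-09 with the block). As a list they shifted in neither direction detectably (median -0.04, camera adjusted p = 0.512).

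Of the gene lists, the REST neuronal targets moved most. This list held 76 genes, of which 39 passed the filter on counts. Members near 0 in siCTRL, such as CHRNB2 and UNC13A, passed it only through the siREST libraries. The share that rose and the median therefore lean upward. In IDHwt 30 of 39 tested members rose and 1 fell (32 and 1 adjusted over the list alone), with a median log2 fold change of 1.64 (camera adjusted p = 2.64e-53; adjusted p = 0.00205 with an estimated correlation). In IDHmut 27 rose and 0 fell by limma (32 and 1 adjusted over the list alone), with a median of 2.08 (camera adjusted p = 4.30e-64; adjusted p = 0.00105 with an estimated correlation). With the replicate block 30 rose and 1 fell in IDHwt (34 and 1 adjusted over the list alone; camera adjusted p = 1.87e-45; adjusted p = 0.00354 with an estimated correlation). In IDHmut it was 31 and 0 (33 and 1 adjusted over the list alone; camera adjusted p = 3.62e-56; adjusted p = 0.00193 with an estimated correlation). No other list held with an estimated correlation, where the smallest adjusted p was 0.467 in IDHwt and 0.910 in IDHmut.

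With the preset correlation 6 lists passed in IDHwt and 5 in IDHmut (9 and 7 with the replicate block). The p53 targets had medians of 0.33 in IDHwt (2 rose, 0 fell; 9 and 0 adjusted over the list alone; adjusted p = 0.755 with an estimated correlation) and 0.18 in IDHmut (adjusted p = 0.995 with an estimated correlation). CDKN1A rose by 0.63 and SESN2 by 0.48 in IDHwt. Cholesterol biosynthesis genes had medians of -0.15 and -0.10, with an adjusted p of 0.943 and 0.995 with an estimated correlation. Ribosomal proteins passed with medians of -0.05 and -0.05, with an adjusted p of 0.943 and 0.995 with an estimated correlation. G2 and M phase genes passed in IDHmut at -0.07 (adjusted p = 0.995 with an estimated correlation). Mitochondrially encoded mRNAs (median 0.30) and replication-dependent histones (0.26) passed in IDHwt alone, each with an adjusted p of 0.833 with an estimated correlation; the difference between lines had an adjusted p of 0.832 and 0.952 with an estimated correlation.

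With the block, p53 targets had 10 rising and 0 falling in IDHwt (17 and 0 adjusted over the list alone; adjusted p = 0.502 with an estimated correlation) and 4 and 0 in IDHmut (9 and 0 adjusted over the list alone; adjusted p = 0.844 with an estimated correlation). Cholesterol biosynthesis had 0 and 7 in IDHwt (0 and 8 adjusted over the list alone; adjusted p = 0.502 with an estimated correlation) and 0 and 2 in IDHmut (0 and 7 adjusted over the list alone; adjusted p = 0.844 with an estimated correlation). In IDHwt the mitochondrially encoded mRNAs had 6 and 0 (12 and 0 adjusted over the list alone; adjusted p = 0.502 with an estimated correlation), and histones 1 and 0 (3 and 0 adjusted over the list alone; adjusted p = 0.502 with an estimated correlation). In IDHmut G2 and M phase genes had 0 and 3 (0 and 4 adjusted over the list alone; adjusted p = 0.958 with an estimated correlation).

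The block added 3 lists in IDHwt and 2 in IDHmut. In IDHwt these were hypoxia (2 rose, 11 fell; 3 and 12 adjusted over the list alone; camera adjusted p = 0.00254; adjusted p = 0.575 with an estimated correlation), the integrated stress response (6 and 2; 7 and 2 adjusted over the list alone; camera adjusted p = 0.00847; adjusted p = 0.575 with an estimated correlation) and neurogenic transcription factors (2 and 0; camera adjusted p = 0.0329; adjusted p = 0.502 with an estimated correlation). In IDHmut they were matrix degradation and invasion (5 and 0; 5 and 2 adjusted over the list alone; camera adjusted p = 0.00776; adjusted p = 0.160 with an estimated correlation) and extracellular matrix structure (4 and 0; 5 and 0 adjusted over the list alone; camera adjusted p = 0.0194; adjusted p = 0.844 with an estimated correlation).

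Without the block, matrix degradation and invasion genes had medians of 0.02 in IDHwt (2 rose, 1 fell; 2 and 2 adjusted over the list alone) and 0.12 in IDHmut (1 rose, 0 fell; 3 and 0 adjusted over the list alone). In IDHwt and then IDHmut, the medians were 0.00 and 0.11 for extracellular matrix structure, -0.04 and -0.02 for mesenchymal transition, -0.07 and -0.03 for integrins and adhesion, 0.07 and 0.04 for TGF-beta and YAP targets and -0.24 and -0.05 for hypoxia. They were -0.04 and 0.06 for astrocyte markers, -0.10 and -0.15 for oligodendrocyte markers, 0.17 and 0.01 for neurogenic transcription factors and -0.03 and -0.03 for the corepressor complex. They were -0.07 and -0.04 for S phase, 0.16 and 0.13 for interferon response, 0.06 and -0.11 for NF-kB cytokines, 0.11 and 0.05 for the integrated stress response and -0.05 and 0.04 for immediate early genes. They were -0.04 and -0.01 for 2-oxoglutarate-dependent dioxygenases, -0.02 and -0.01 for DNA methylation factors, 0.27 and -0.39 for epithelial markers and 0.08 and -0.19 for endothelial markers.

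REST binding was mapped in each line by ChIP-seq. The samples had 3569 and 3623 peaks in IDHwt and 2752 and 2387 in IDHmut, with median fold enrichments of 13.9, 13.3, 12.1 and 13.1. Reproducible regions numbered 2950 in IDHwt and 2013 in IDHmut. The strongest in IDHwt lay in VRK3 (chromosome 19, 49986865 to 49987811, mean fold 110), at NOL9 (1, 6554184 to 6554797, 101), in SYT7 (11, 61566841 to 61568217, 100.4), at ERCC6L2 (9, 95875259 to 95875895, 100.3) and at MAP2K2 (19, 4123854 to 4124450, 99.5). The strongest in IDHmut lay in NPAS4 (11, 66421108 to 66422565, 91.3), 16197 bp from DYNC1H1 (14, 101947950 to 101948376, 88.3), in SHANK2 (11, 70649869 to 70650914, 85.5), at DENR (12, 122752616 to 122753061, 84.7) and 4268 bp from SIGLEC10 (19, 51421910 to 51422684, 84.2). Regions within 1 kb of a gene end made up 39.7% in IDHwt and 38.5% in IDHmut, regions inside genes 36.8% and 37.5%, and regions outside genes 23.5% and 24.0%.

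The REST regions of IDHmut were nearly all present in IDHwt, and fewer regions went the other way. Of the IDHmut regions 94.4% were also reproducible in IDHwt, and 66 (3.28%) had no peak in either IDHwt sample. Of the IDHwt regions 64.4% were reproducible in IDHmut, and 629 (21.3%) had no peak in either IDHmut sample. The share of peaks of a sample that overlapped a peak of another averaged 80.6% within a line and 73.8% between lines. It was 82.1% to 82.8% for IDHwt peaks within the line and 57.9% to 63.4% in IDHmut samples. For IDHmut peaks it was 73.2% to 84.4% within the line and 76.1% to 93.6% in IDHwt samples. An alternative added after the data were seen used only the 1000 top peaks of each sample. Of these reproducible regions, 8.70% in IDHwt and 10.8% in IDHmut overlapped no top peak of the other line. They may still overlap a weaker peak there, so they are not line-specific as defined above.

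Line-specific regions were weak. Of the IDHwt-specific regions, 95.2% lay below the median fold of IDHwt regions. The share of IDHwt regions without an IDHmut peak was 56.4% in the weakest quartile by fold, 24.8% and 4.07% in the next quartiles and 0% of 738 in the strongest. For IDHmut regions without an IDHwt peak the shares were 7.14%, 4.57%, 1.39% and 0%. Between samples of IDHwt, peaks of sample 1 without a peak in sample 2 made up 46.1%, 20.4%, 1.93% and 0% of the quartiles. These are peaks of a single sample set against 1 other sample, so their shares are not like for like with those of reproducible regions. The strongest IDHwt-specific regions lay on chromosome 5 (97629289 to 97629617, inside a non-coding RNA gene, 446042 bp from RIOK2), 65 bp from SPTSSA, 50098 bp from GABRG3, in CD320 and 99510 bp from AGAP1, with mean folds of 25.3, 25.2, 25.0, 22.8 and 21.5. The strongest IDHmut-specific regions lay in DMD, inside non-coding RNA genes 218778 bp from DIAPH2 and 64171 bp from ELAVL4, 1826 bp from PCDH8 and inside a non-coding RNA gene on chromosome 8 (64379945 to 64380233), with mean folds of 23.1, 23.04, 22.95, 20.7 and 18.7. No change in binding at a single region was tested, because signal over common regions was not counted here and each line had 2 samples.

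**Figure D3:**
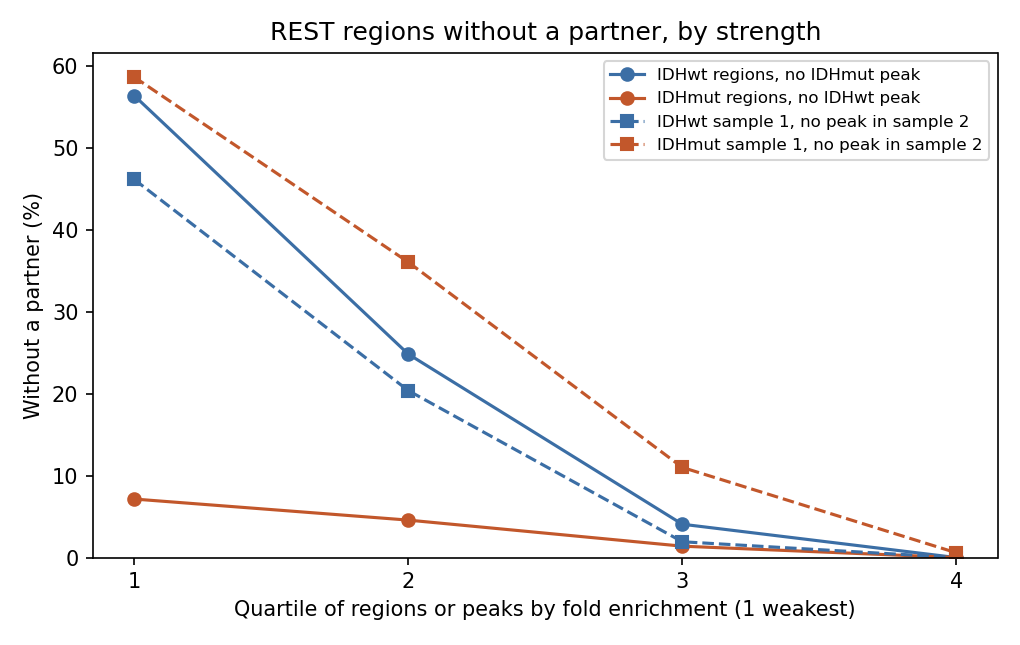
Percent of REST regions or peaks without a partner (y axis) by quartile of fold enrichment, 1 being the weakest (x axis); solid lines show reproducible regions of a line with no peak in either sample of the other, and dashed lines show peaks of sample 1 with no peak in sample 2 of the same line. The solid IDHwt line falls from 56.4% to 0% and the solid IDHmut line from 7.14% to 0%. The dashed IDHwt line falls from 46.1% to 0% and the dashed IDHmut line from 58.6% to 0.584%.

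Whether REST-bound genes were those that rose was asked by joining the peaks with siREST changes of the same line. CHRNB2, UNC13A, SYP, SCG2, STMN3, RUNDC3A, CHGB and TMEM198 were the bound genes with the largest mean rise over both lines. Their peak folds were 66.6 and 49.9 at CHRNB2, 25.6 and 15.4 at UNC13A, 59.4 and 37.9 at SYP, and 42.9 and 37.5 at SCG2, in IDHwt and IDHmut. At STMN3 they were 22.2 and 32.0, at RUNDC3A 57.5 and 43.6, at CHGB 63.0 and 57.5, and at TMEM198 43.9 and 39.6. VGF had no reproducible region within 1 kb of either gene end in either line. Regions further inside a gene did not count as binding under this definition, so binding of REST within VGF stays open.

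Rising genes were bound far more often than other genes, and falling genes were not. In IDHwt 92 of 250 rising genes (36.8%) were bound, against 7.66% of other genes (odds ratio 7.02, 95% interval 5.38 to 9.14, Fisher's exact p = 1.91e-37; odds ratio 2.86 with the replicate block). In IDHmut 69 of 143 (48.3%) were bound, against 4.76% (odds ratio 18.6, 13.3 to 26.1, Fisher's exact p = 2.46e-50; 6.03 with the block). Of the falling genes, 13 of 197 were bound in IDHwt (odds ratio 0.79, Fisher's exact p = 0.512) and 3 of 79 in IDHmut (odds ratio 0.72, Fisher's exact p = 0.799; odds ratio 1.13 with the block, Fisher's exact p = 0.573). Of 124 placed genes that rose in both lines, 67 (54.0%) were bound in both, against 5.14% of all placed genes. An alternative chosen after seeing the data also counted regions inside the gene. It gave 117 of 250 rising genes bound in IDHwt (46.8%, against 11.4% of other genes) and 87 of 143 in IDHmut (60.8%, against 7.09%). Genes are not independent replicates, and the 2 lines have different numbers of regions, so the odds ratios are not compared between them.

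The share of genes that rose went up with peak strength, and most bound genes were not called. In IDHwt 12.2% of genes in the highest tertile of peak fold rose (Wilson interval 9.27% to 15.9%), 7.69% in the middle, 4.51% in the lowest and 1.25% without a peak. In IDHmut these shares were 18.3% (13.95% to 23.7%), 6.25%, 4.17% and 0.565%. Genes without such a peak included 158 that rose in IDHwt and 74 in IDHmut. Whether REST acts on these directly was not tested.

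**Figure D4:**
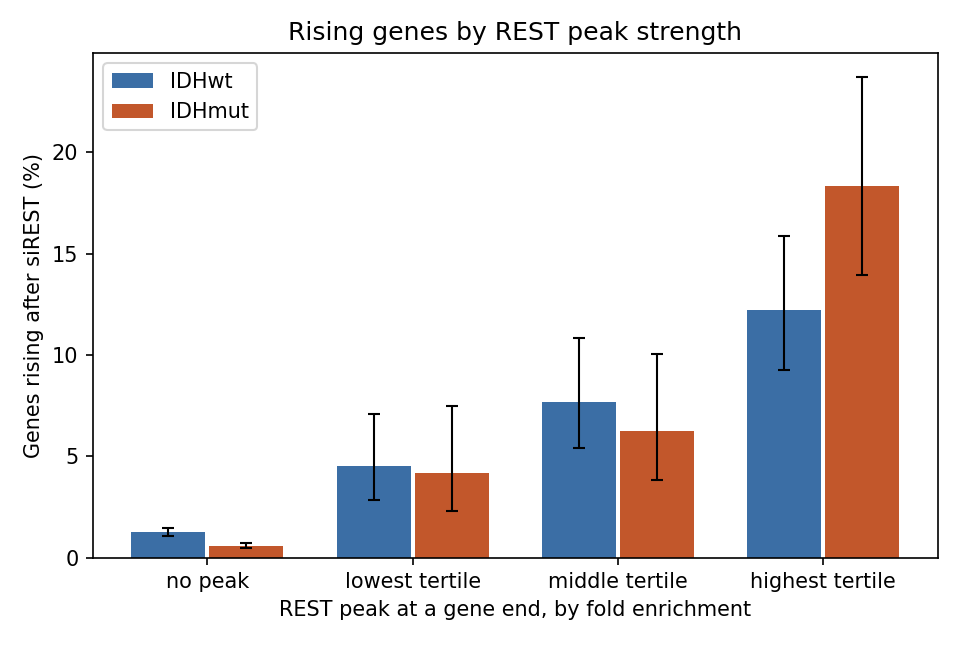
Percent of genes that rose after siREST (y axis) without a REST peak at a gene end and by tertile of peak fold enrichment (x axis), in IDHwt (blue) and IDHmut (orange); error bars are Wilson 95% intervals. The share goes from 1.25% to 12.2% in IDHwt and from 0.565% to 18.3% in IDHmut.

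How the lines differ without REST knockdown was asked first in untreated cells. The epithelial protease inhibitor PI3 and the serpins SERPINB4 and SERPINB3 were among the genes highest in IDHmut relative to IDHwt, with the germline gene DAZL, MAGEL2, FAM133A and the thyroid hormone deiodinase DIO2. Genes of the extracellular matrix were among the lowest: SNED1, MFAP4 and PCOLCE, with the transcription factor FOXS1, DNALI1, PLXDC1, SLC30A4 and AK5.

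PI3 was 10.22 higher on the log2 scale (SE 0.623, adjusted p = 2.44e-05), DAZL 7.98, SERPINB4 6.72, MAGEL2 6.36, SERPINB3 6.26, FAM133A 6.07 and DIO2 6.04. The IDHmut libraries spread widely for PI3 (10910 ± 7456), SERPINB4 (5022 ± 3875), SERPINB3 (386 ± 347), DAZL (792.1 ± 374) and DIO2 (280.9 ± 135; SD, n = 3). The spread was smaller for MAGEL2 (105.7 ± 25.5) and FAM133A (174.8 ± 24.3). SPRR2A was at 110.2 ± 77.8 normalized counts in IDHmut (SD, n = 3) and listed at 0 in all IDHwt libraries. MAGEL2, FAM133A and DAZL had mean counts of 0.351, 1.66 and 1.99 in IDHwt, so the added count of 1 affects the size of their differences. PCOLCE was at 223.9 ± 43.5 in IDHmut and 3853 ± 295 in IDHwt, a log2 difference of -4.11 (SE 0.133, adjusted p = 1.20e-06). The log2 differences were -6.13 for SNED1, -5.69 for FOXS1, -4.66 for DNALI1, -4.59 for PLXDC1, -4.52 for MFAP4, -4.15 for SLC30A4 and -4.02 for AK5. Of 14213 genes, 2828 were higher and 2922 lower in IDHmut. The count was 3757 without untreated_IDHwt replicate 2. At least a 2-fold difference was seen for 651 higher and 902 lower genes. These were 402 and 830 without untreated_IDHmut replicate 1, and 444 and 890 without untreated_IDHmut replicate 2. Each line is a single line, so the line and the IDH1 genotype cannot be parted.

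The siCTRL libraries gave a comparison of the lines in separate libraries. PI3 was 9.29 higher in IDHmut, EMILIN2 6.89 and MMP3 6.79 on the log2 scale, and TESPA1 was at 150.8 ± 11.1 (SD, n = 3) against 0 in all IDHwt libraries. MEG3 was at 0 in all IDHmut libraries and 449.9 ± 25.7 in IDHwt. ADGRL2 was at -8.07, SARDH at -7.90 and MTMR1 at -7.82 on the log2 scale. Mean counts in IDHmut were 4.31 for ADGRL2, 0.330 for SARDH and 0.337 for MTMR1, so the added count of 1 affects the size of these values. In siCTRL libraries 3177 genes were higher and 3554 lower. Called in both tables were 1725 higher genes (589.5 if independent) and 2066 lower genes (707.4 if independent), while 103 had opposite calls. Of the untreated calls 67.3% were called in the same direction in siCTRL, and across genes the differences had a Pearson r of 0.79.

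Among the gene lists, matrix genes were lower and inflammatory cytokines higher in IDHmut. Extracellular matrix structure had 3 higher and 21 lower of 30 untreated (4 and 25 adjusted over the list alone; median -0.89; adjusted p = 0.678 with an estimated correlation), and 5 and 16 in siCTRL (5 and 17 adjusted over the list alone; median -0.54; adjusted p = 0.787 with an estimated correlation). LAMC1 was at -0.86, LAMB1 at -1.01, THBS2 at -1.16 and SPP1 at -1.06 untreated. NF-kB cytokines had 15 higher and 4 lower of 22 untreated (15 and 4 adjusted over the list alone; median 2.07; adjusted p = 0.713 with an estimated correlation) and 11 and 0 of 19 in siCTRL by limma (11 and 0 adjusted over the list alone; median 1.48; adjusted p = 0.787 with an estimated correlation). CSF2 was higher by 2.69, SOD2 by 1.44, LIF by 3.05 and PTGS2 by 3.97 untreated. Matrix degradation and invasion genes went both ways, with 8 higher and 11 lower untreated (10 and 11 adjusted over the list alone): CTSK was at -3.36, ADAM8 at -2.38, FAP at -1.50 and CTSB at -1.10, while MMP3 was at 6.79 in siCTRL.

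With the preset correlation 6 lists passed untreated and 8 in siCTRL, and 0 with an estimated correlation, where the smallest adjusted p was 0.678 and 0.787. In addition to the matrix and cytokine lists, these were mesenchymal transition (median -0.47), S phase (0.31), p53 targets (0.29) and the integrated stress response (0.44) untreated, each with an adjusted p of 0.678 to 0.821 with an estimated correlation. In siCTRL they were mitochondrially encoded mRNAs (0.72), p53 targets (0.42), cholesterol biosynthesis (-0.28), TGF-beta and YAP targets (-0.55), ribosomal proteins (0.12) and S phase (0.15), each with an adjusted p of 0.787 to 0.832 with an estimated correlation. REST neuronal targets had 9 higher and 9 lower of 31 untreated (10 and 9 adjusted over the list alone; median -0.07) and 18 and 12 of 39 in siCTRL (18 and 12 adjusted over the list alone; median 0.51). NRCAM was at 3.39 and GDAP1 at -1.15 untreated. By fry for a shared direction, which does not compare a list with other genes, 10 lists passed untreated and 13 in siCTRL.

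Most genes of chromosome 14 and of the distal part of chromosome 1 were lower in IDHmut, a comparison added after the data were seen. The median log2 difference of chromosome 14 genes was -0.52 untreated and -0.64 in siCTRL, with 87.9% and 89.7% of its genes below 0. For chromosome 1 from 140 Mb it was -0.42 and -0.46, with 67.1% and 66.2% below 0 and 96 and 102 genes called higher. Segments of 10 Mb with a median of -0.5 or below in both tables lay at 140 to 180 and 240 to 250 Mb of chromosome 1 and at 20 to 50 and 100 to 110 Mb of chromosome 14. For all other genes it was 0.02 in each table, and siREST moved chromosome 14 by a median of -0.02 in IDHwt. In the 9 IDHmut libraries, the chromosome 14 median ranged from -0.66 to -0.48. Without these segments, 4839 of the 5550 placed calls were left untreated, and 5606 of 6411 in siCTRL. Higher and lower genes went from 2730 and 2820 to 2612 and 2227 untreated, and from 2979 and 3432 to 2855 and 2751 in siCTRL.

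**Figure D5:**
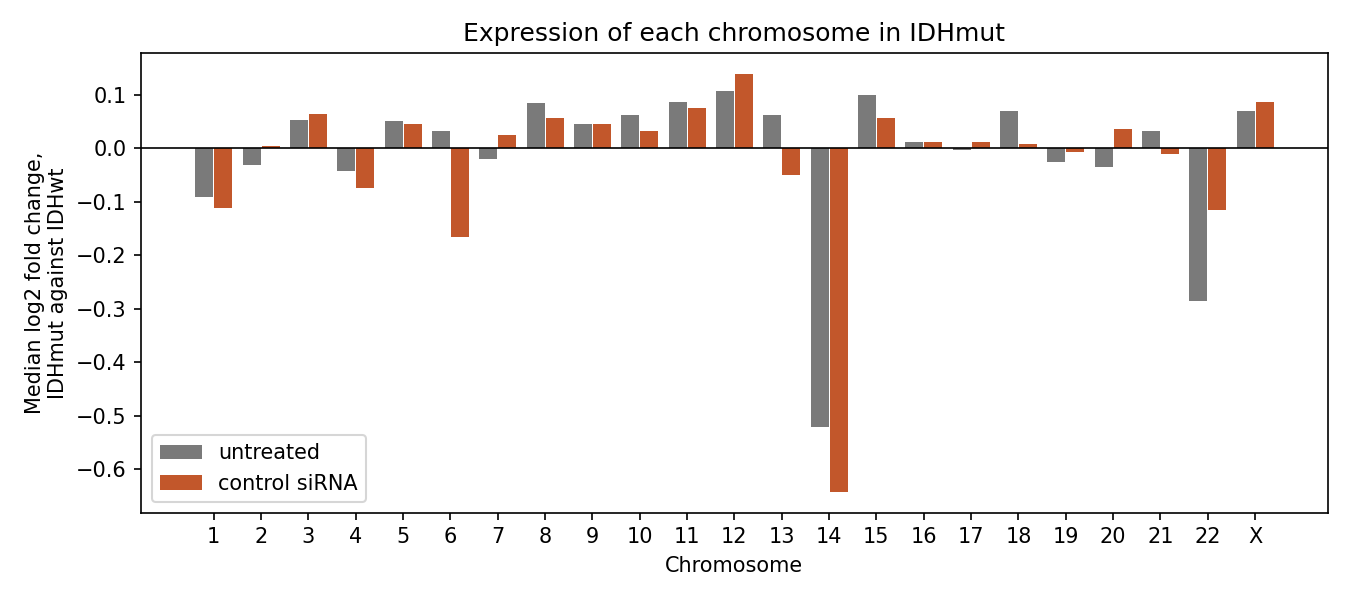
Median log2 fold change of IDHmut against IDHwt (y axis) over the tested genes of each chromosome (x axis), in untreated (grey) and siCTRL (orange) libraries. Chromosome 14 lies at -0.52 and -0.64; the next lowest median is -0.28, for chromosome 22 untreated.

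Whether the genes that change after siREST differ between the untreated lines was asked across contrasts with no shared libraries. The siREST change in IDHwt and the untreated line difference had a Pearson r of 0.054 and a Spearman rho of 0.041 across genes. Genes rising after siREST in IDHwt were over-represented among genes higher in IDHmut (79 against 48.3 if independent, odds ratio 1.97, Fisher's exact p = 2.95e-06), and so were genes falling after siREST (60 against 39.9, odds ratio 1.73, Fisher's exact p = 0.000657). With the replicate block 223 rising genes were higher against 148.6 (odds ratio 1.77, Fisher's exact p = 2.70e-11). Falling genes were then over-represented among higher genes (193 against 152.2, Fisher's exact p = 0.000238) and among lower genes (203 against 161.0, Fisher's exact p = 0.000191). In IDHmut 35 rising genes were higher against 26.5 (odds ratio 1.44, Fisher's exact p = 0.0801; Fisher's exact p = 0.0453 with a mean of at least 50 and 0.0439 with a prior count of 5) and 33 were lower against 27.5 (odds ratio 1.27, Fisher's exact p = 0.237), with an r of 0.000488 across genes. With the block in IDHmut it was 103 against 89.7 (odds ratio 1.20, Fisher's exact p = 0.120), and 131 rising genes were lower against 94.9 (odds ratio 1.55, Fisher's exact p = 5.10e-05). Genes falling in IDHmut were over-represented with the block among higher genes (115 against 79.2, Fisher's exact p = 1.44e-05) and lower genes (103 against 83.8, Fisher's exact p = 0.0213). Genes are not independent replicates, so these Fisher p values overstate the evidence where genes move together. Genes at IDHwt-specific REST regions (250 tested) had a median difference of 0.0025 untreated, with an adjusted p of 0.698 by camera with an estimated correlation. By fry for a shared direction, which does not compare them with other genes, they were lower in IDHmut (adjusted p = 0.0101, and 0.0986 with the replicate block).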

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

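The tests of explanations in this part were chosen after the results they weigh had been seen.

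The siREST change of 3 gene lists differed between the lines by camera with the preset correlation. Mitochondrially encoded mRNAs moved lower in IDHmut relative to IDHwt (median difference -0.41, adjusted p = 9.74e-11), with a median change of 0.30 in IDHwt and 0.00 in IDHmut. The p53 targets (median -0.13, adjusted p = 0.0129) and the replication-dependent histones (median -0.22, adjusted p = 0.0129) also moved lower. None of the 3 held with an estimated correlation, where the adjusted p was 0.832, 0.952 and 0.952.

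For the mitochondrially encoded mRNAs, a single library as the source stays open. Same-numbered libraries correlated within each line, so the list mean was compared by pair. It rose in all 3 IDHwt pairs, by 0.58, 0.11 and 0.37, and changed by -0.08, -0.11 and 0.13 in the IDHmut pairs. The difference between lines was -0.37 (SE 0.154, 95% interval -0.80 to 0.06; SE 0.241 unpaired). Without the pair of IDHwt replicate 1 it was nearest to 0, at -0.26 (95% interval -0.69 to 0.17). Without the pair of IDHwt replicate 2 it was -0.49 (95% interval -0.89 to -0.09). With the replicate block, 10 of 13 members fell in IDHmut relative to IDHwt adjusted over the list alone (0 without it), and MT-ND1 and MT-ND2 were called with a block within each line. The block gave an adjusted p of 0.519 with an estimated correlation (0.0469 unadjusted). The difference kept its sign whichever pair was left out, but most of these intervals included 0. Correlation between the genes of the list stays open, since the adjusted p was 0.832 with an estimated correlation; these mRNAs come from shared transcripts and tend to move together between libraries. A difference between the lines in mitochondrial transcripts after REST knockdown was not tested otherwise and stays open.

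Other splits of the same libraries were counted for each contrast. The 10 splits of 6 libraries, and the 4 swaps of pairs, are too few for a share under 0.05. For siREST in IDHwt the real split called 456 genes and the highest other split 1 (1 of 10 as large); with the replicate block it was 1608 against 0 (1 of 4). For siREST in IDHmut it was 226 against 0 (1 of 10), and with the block 912 against 0 (1 of 4). For the lines it was 6731 against 0 in siCTRL and 5750 against 0 untreated (1 of 10 each). For gene lists with the preset correlation, the real split called 6 lists in IDHwt and the highest other split 13, with 9 of 10 splits as large. In IDHmut it was 5 against 14 (9 of 10), in siCTRL 8 against 8 (3 of 10) and untreated 6 against 9 (4 of 10). For the interaction, the real labels called 0 genes by limma (283 at an unadjusted p under 0.05, 0 by edgeR and 4 by DESeq2). All 100 drawn splits were therefore as large by definition, and this comparison cannot decide anything. The highest called 3120, where line labels were exchanged for all siCTRL libraries and for 1 siREST library of each line, so that split follows the difference between the lines.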

How the results depend on the processing

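Most alternatives were set before the data were examined. The block within each line, edgeR with the block, 2 groups with the block, the 1000 top peaks and regions inside genes were chosen after seeing the data. REST changes after siREST, the REST-target list, shares of bound genes among rising genes and peak numbers per sample kept their direction and side of the threshold under the alternatives run. The REST change ranged from -1.69 to -1.60 in IDHwt and from -2.00 to -1.78 in IDHmut. Of 1015 values for named genes, 973 kept direction and call, 42 lost the call and 0 reversed. The cause was not tested for the changes below, unless the construction gives it.

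The replicate block, a paired fit, raised the siREST counts from 456 to 1608 in IDHwt and from 226 to 912 in IDHmut, and the interaction from 0 to 4 genes. Block fits also gave 2477, 1554 and 18 with a block within each line, 1725, 892 and 5 by edgeR, and 2905 and 1564 with 2 groups alone. With the block, same-direction line calls rose from 67.3% to 75.8%, and interaction lists from 3 to 5 (0 with the block and an estimated correlation). The odds ratio for a peak at genes falling in IDHmut went from 0.72 to 1.13, past the threshold in neither.

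Leaving out a library gave 194 to 406 calls in IDHwt, 105 to 599 in IDHmut, 0 to 2 for the interaction and 3757 to 6027 for the untreated lines; some of these fits called more genes than all libraries did. The extremes were without siREST_IDHwt replicates 2 and 1, siREST_IDHmut replicates 2 and 1, siCTRL_IDHwt replicate 3 and, untreated, IDHwt replicate 2 and IDHmut replicate 2. A fit on 2 groups alone called 112 genes in IDHmut.

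A 2-fold minimum left 87, 58, 1553 and 1732 genes for siREST in IDHwt, siREST in IDHmut, the untreated lines and the siCTRL lines. The interaction, 0 by limma (283 at an unadjusted p under 0.05, 0 by edgeR), was 1 with a prior count of 5, 3 without a filter and 4 by DESeq2. The estimated correlation left 1, 1, 0, 0 and 0 lists of 6, 5, 3, 6 and 8.

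A 50% reciprocal overlap gave 77.9% within and 64.6% between lines, and the 1000 top peaks 84.8% and 78.3%. The top peaks left 851 IDHwt and 845 IDHmut regions, by construction. Of these, 74 IDHwt regions overlapped no top peak of IDHmut, which does not exclude a weaker peak there. The RE1 motif alternative was not run, as no genome sequence was used here. Of simulated 1.5-fold interactions, 40% were recovered, in genes with a mean of at least 50 normalized counts. Replicate variance was 4.68 to 27.7 times counting noise in the siRNA table and 3.55 to 49.2 times in the untreated table, so spread between libraries exceeded counting noise.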

Other observations

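The tests of explanations and of the hypothesis in this part were chosen after the results they weigh had been seen.

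Genes of chromosome 14 and of chromosome 1 from 140 Mb were lower in IDHmut. The authors' normalization as the cause was argued against, since 1 factor per library moves all genes alike. In the IDHmut libraries the segment median minus that of all other genes was -0.69 to -0.40 on the log2 scale, while in IDHwt libraries the difference was at most 0.0131 in size. These values do not add to that argument, because the segments were chosen for lying low in IDHmut. Each library was also measured against the IDHwt mean, which keeps the IDHwt values near 0. A lower DNA copy of these segments in IDHmut cannot be told apart from regional silencing: 89.7% of chromosome 14 genes lay below 0 in siCTRL, but the segments were chosen for this pattern and no DNA data were used here.

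REST regions called in IDHwt without a peak in either IDHmut sample were mostly weak. Lower DNA copy of the chromosome 14 and chromosome 1 segments could account only for regions inside them. Of the regions without an IDHmut peak, 89.8% lay elsewhere, so lower copy cannot be the whole source. That outcome was fixed in advance, because the segments held 211 IDHwt regions while 629 had no IDHmut peak. A contribution of lower copy stays open, as 30.3% of IDHwt regions inside the segments (64 of 211) and 20.6% elsewhere (565 of 2739) had no IDHmut peak. Weaker enrichment in the IDHmut ChIP samples stays open. Of the weakest quartile of IDHwt regions 56.4% had no IDHmut peak, and of the strongest 0%. For IDHmut regions without an IDHwt peak these shares were 7.14% and 0%. Shares between samples of 1 line also fell, from 46.1% to 0% in IDHwt and from 58.6% to 0.584% in IDHmut. Those are peaks of a single sample missing from 1 other sample, so their size cannot be set against the shares of reproducible regions. An effect of the IDH1 genotype on REST occupancy cannot be told apart from the other differences between the lines: genes at these regions gave p = 0.558 by camera with an estimated correlation, and binding strength was not measured across lists.

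Genes rising after siREST in IDHwt were over-represented among genes higher in untreated IDHmut. The hypothesis that REST repression might be weaker in IDHmut was tested on the 67 genes bound and rising in both lines. Of the 59 tested untreated, 15 were higher and 14 lower by call, with a median difference of -0.09 (p = 0.938 by camera with an estimated correlation), which leaves the hypothesis open. Genes falling after siREST were over-represented too, so the overlap was not specific to genes that rise after siREST. For genes rising in IDHmut, 35 were higher against 26.5 if independent (Fisher's exact p = 0.0801; 0.0453 with a mean of at least 50 and 0.0439 with a prior count of 5) and 33 lower against 27.5 (Fisher's exact p = 0.237). With the replicate block 103 were higher against 89.7 (Fisher's exact p = 0.120) and 131 lower against 94.9 (Fisher's exact p = 5.10e-05). The difference between the fits was not tested. These Fisher p values treat genes as independent replicates, which they are not.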
